A study of Mus musculus with 10 samples.

How the data were processed

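Hepatocytes of 10 male wild-type C57BL/6J mice, 5 young and 5 old, were profiled by whole-genome bisulfite sequencing, which reads an unmethylated cytosine as thymine and leaves a methylated one as cytosine. Per the labels, DNA was extracted with a Zymo quick-DNA miniprep kit and sheared, and the libraries were end-repaired, A-tailed, ligated to methylated adapters and then treated with bisulfite. Mice numbered 1 to 4 in each group were culled on 1 date, at 162 days (young) and 774 days (old). Mouse 5 of each group was culled on an earlier date, at 161 and 757 days.

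The authors deposited 1 table for all mice, that lists each cytosine of a CpG by strand. Per the submitters' processing notes reads were aligned with Bismark to GRCm38 (mm10). The Bismark version, trimming, removal of duplicate reads and any coverage filter are not given in the sources used here. The authors gave for each cytosine and mouse a methylation level as a percent, and per the file headers a second column whose values are the count of reads covering the cytosine. The deposited percent times the count was a whole number of methylated reads within 0.01 for every value, so methylated and unmethylated read counts could be recovered without loss. The table holds 38805976 cytosines, each covered in every mouse. Both strands of each CpG were summed, which gave 20558963 CpGs, of which 88.8% had both strands. The 28779 cytosines on 36 unplaced scaffolds were not paired and entered no region or test of methylation. They are still counted in these totals and in the mean depth per CpG.

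Mean depth was 16.8 to 21.4 reads per CpG. Depth limits the precision of single CpGs, so reads were summed over regions before testing. The regions were non-overlapping 1 kb tiles, 100 kb bins, inferred promoters and gene bodies. The reference at hand gave gene starts and ends on GRCm38 but no strand, exons or sequence. The 5′ end of a gene was therefore inferred without regard to age, as the end whose surrounding 1 kb on either side held more CpGs and a lower level over all mice. This gave a 5′ end to 16469 of 21639 genes. Among Hox genes, whose strand is known from their clusters, 27 of 30 inferred ends lay on the known side. A promoter was 1 kb on either side of the inferred end, and a gene body was the gene without 1 kb at each end, for genes of at least 3 kb (planned as 2 kb, which would have left bodies of no length once both ends were trimmed). Exons, introns, repeats and isolated CpGs flanked by A or T had been planned as compartments and could not be made without strand, exons and sequence.

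Tiles, promoters and gene bodies needed at least 3 CpGs and 20 reads in every mouse, and bins 50 CpGs and 500 reads. Old and young mice were compared with a logistic model on methylated and unmethylated reads and a quasi-likelihood F test. The dispersion was moderated by empirical Bayes within 20 bins of like coverage and floored at 1. P-values were adjusted by Benjamini-Hochberg over all regions of a kind, and a region was called at an adjusted p under 0.05. This model was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0. Figures were drawn with matplotlib 3.10.9. Values with 1 number per mouse were compared by a two-sided exact permutation test over all 252 assignments of 5 against 5, whose smallest p is 0.00794. These were the global level (autosomal CpGs with at least 5 reads in every mouse), 26 compartments, 18 gene lists each for promoters and gene bodies, the share of tiles between 20 and 80%, and the spread between mice. The last 2 used tiles with at least 50 reads in every mouse. Levels are unweighted means of mice with their SD, n = 5 in each group unless stated.

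The model was tested on simulated data with the depths and levels of the real mice. Dispersions were drawn from the prior fitted to the real data, and regions were simulated independently of each other. Traits that a mouse shares over many regions were thus left out, and a share near 5% without a difference was largely built in. Without a difference, 4.94 to 5.07% of regions had an unadjusted p under 0.05. Of the simulated regions called after adjustment 7.35% of tiles, 5.29% of promoters, 3.14% of gene bodies and 6.60% of bins were false, above the nominal 5% for 3 of the 4. A difference of 10 points was recovered in 14.9% of tiles, 91.0% of promoters, 97.0% of gene bodies and 100% of bins, and a difference of 20 points in 80.3% of tiles. Only 200 regions of each kind were changed, so that these shares do not carry over to data with more differences.

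The tests, gene lists and main alternatives were chosen before the data were examined. The lists were interferon-stimulated genes, interferon receptors, sensors and signalling, antigen presentation, hepatocyte identity, xenobiotic, bile acid and lipid metabolism, developmental transcription factors, imprinted genes, cell cycle and tumour suppression, inflammation, DNA methylation machinery, housekeeping genes, and markers of 7 other cell types (leukocytes in general, T cells, B cells, macrophages, endothelium, stellate cells or fibroblasts, and cholangiocytes). Named genes followed a rule fixed at the same time. It took the 12 called promoters and the 12 called gene bodies with the largest difference on each side and at least 5 CpGs, up to 4 called members per list or else the 2 with the smallest p, and a few genes always shown. For tiles it took the 8 largest on each side without overlap between the groups. Predicted genes without a name were passed over, and some genes that met the rule are not reported here.

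The alternatives were other coverage minimums, tile, bin and promoter sizes, cull date or replicate number as a term, the genome-wide level as an offset, no moderation, no dispersion floor, a minimum difference of 10 points, limma 3.58.1 on log2 ratios with a pseudocount of 1, edgeR 4.0.16 for promoters (both in R 4.3.3), random matched lists, medians, mice of the later date alone, and leaving out each mouse. Alternatives chosen after the data were seen were surer 5′ ends (ends differing by at least 20 points), both ends of every gene, exclusion of CpGs read all-or-none by group, and exclusion of regions deeper than 2 times the median. The main comparison had no block.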

Results

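Methylation of CpGs was measured across the genome in hepatocytes of 5 young mice (161 to 162 days) and 5 old mice (757 to 774 days), to ask how the hepatocyte methylome differs with age. Mean depth at a CpG was 18.6 ± 1.53 reads (SD, n = 5) in young and 20.03 ± 1.31 (n = 5) in old mice and did not differ detectably (exact permutation p = 0.183). Young replicates 1 to 5 had 16.8, 17.7, 19.05, 20.9 and 18.8 reads per CpG, and old replicates 1 to 5 had 21.1, 18.3, 20.3, 21.4 and 19.04. Intervals and SDs cover mice and counting error, not loss of molecules before sequencing.

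No difference in the genome-wide level of methylation was detected between the age groups. Autosomal CpGs were methylated at 75.7% ± 0.442 (SD, n = 5) in young and 75.5% ± 0.791 (n = 5) in old mice (exact permutation p = 0.675). Old replicate 1 had the lowest level of the 10, 74.5%, and without it the difference turned from -0.19 to 0.060 points. CpG-dense tiles, those with at least 40 CpGs in 1 kb, stood at 13.0% ± 0.535 in young and 14.2% ± 0.558 in old mice, but none of 26 compartments passed adjustment. For the dense tiles the exact permutation p was 0.0238 and the adjusted p 0.619, and the lowest adjusted p of any compartment ranged from 0.206 to 1 over the alternatives. Since 0.00794 is the smallest p the mice allow, a compartment alone could not pass adjustment over 26. The 0 calls came from exact permutation tests, 1 of which had an unadjusted p under 0.05, and no other tool was run on compartments. Sparse tiles (80.1% and 79.9%), gene bodies (79.2% and 78.9%), inferred promoters (14.9% and 15.2%), intergenic CpGs (78.2% and 78.0%) and chromosome X (78.5% and 78.2%) differed by less than the spread between old mice. The share of 1 kb tiles between 20 and 80% methylated was 35.5% ± 1.38 in young and 36.2% ± 3.55 in old mice (exact permutation p = 0.825), and without old replicate 1 the difference turned from 0.694 to -0.826 points.

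The inferred promoters of 333 of 16446 genes differed between the age groups, 215 higher and 118 lower in old mice. This direction did not hold throughout: of those that differed by at least 10 points 22 were higher and 42 lower, and with both ends of every gene 332 were higher and 540 lower. The gain was greatest at Nr2f2, which encodes the orphan nuclear receptor COUP-TFII. Its inferred promoter (gene 11819, chromosome 7, 70350946 to 70352946) rose from 16.6% ± 0.954 in young to 39.4% ± 4.38 in old mice (SD, n = 5 each), over 55 CpGs and 503 to 811 reads per mouse (adjusted p = 8.1e-08). The promoter of Scx, which encodes the tendon transcription factor scleraxis (gene 20289, chromosome 15), rose from 63.7% ± 1.21 to 77.5% ± 1.09. Lrrc4c, which encodes a synaptic adhesion protein (gene 241568), rose from 30.8% ± 2.37 to 51.7% ± 5.73, Ankmy1 (gene 241158) from 30.1% ± 2.20 to 44.1% ± 3.68, and Map10, a microtubule-associated protein (gene 74393), from 35.9% ± 1.55 to 48.3% ± 2.81. At each of these 5 inferred promoters the 5 old mice lay above all young mice, and each call held under every alternative. The strand of these genes was not in the reference, so that any of these windows may lie at a 3′ end. Sh3bgrl3, Lrrc4 and Nupr1 rose by 12.2 to 13.3 points, the last 2 only with some window sizes: with 250 bases on either side Lrrc4 had an adjusted p of 0.169 (range over alternatives 0.000737 to 0.169) and Nupr1 one of 0.868 (0.000463 to 0.868). Ptk7, a receptor of the Wnt pathway, stood at 25.8% ± 3.94 and 46.3% ± 3.43 over 1 kb on either side, but with 250 bases the difference turned to -1.06 points (adjusted p 0.946, range 1.2e-06 to 0.946).

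Among promoters that lost methylation, Ffar2, a receptor for short-chain fatty acids (gene 233079, chromosome 7, 30822775 to 30824775), fell from 79.7% ± 1.64 to 65.3% ± 2.53 (SD, n = 5 each, 31 CpGs, adjusted p = 1.2e-05), and the call held under every alternative. Acot8, a peroxisomal acyl-CoA thioesterase (gene 170789), fell from 61.6% ± 3.63 to 39.2% ± 3.65. Pigr, which carries IgA across epithelia (gene 18703), fell from 50.5% ± 5.47 to 33.1% ± 2.20. Slc3a1, a subunit of a cystine transporter (gene 20532), fell from 61.1% ± 5.10 to 45.6% ± 6.02, and Fetub, the plasma protein fetuin-B (gene 59083), from 72.6% ± 5.94 to 59.1% ± 4.11. Cdh19, Omp and Chil6 fell by 23.9, 15.6 and 15.1 points. With a window of 250 bases the calls at Acot8 (adjusted p 0.123, range 7.6e-07 to 0.123), Pigr (0.212, range 1.1e-10 to 0.292), Slc3a1 (0.393, range 6.1e-05 to 0.393) and Chil6 (0.210, range 3.4e-05 to 0.210) were lost. Tmem267, Rpl32l, Vmn2r29 and Zscan4b also fell, while Vamp9, Olfr102 and Olfr391 rose, Olfr102 by 13.7 and Olfr391 by 13.5 points. All of these passed, but belong by name to gene families or have copies elsewhere, and how surely their reads were placed was not tested. Olfr102 was lost without young replicate 3 (adjusted p 0.0722), Olfr391 without any 1 mouse other than old replicate 5 (up to 0.150), and Zscan4b without young replicate 3, 4 or 5 or old replicate 2 or 5 (up to 0.104). CpG-rich promoters, with at least 80 CpGs in 2 kb, made up 159 of the promoters that rose and 15 of those that fell. Without young replicate 4 the calls dropped to 213.

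Promoters of developmental transcription factors, which pattern the embryo and are silent in hepatocytes, gained methylation in old mice. Their mean rose from 4.77% ± 0.0916 to 6.39% ± 0.443 (SD, n = 5), with all 5 old mice above all young mice (exact permutation p = 0.00794, adjusted over 18 lists 0.0476). Of 71 measured members 16 rose and none fell over all genes tested, and 46 rose when adjusted over the list alone. Gbx2, a homeobox gene of the midbrain and hindbrain (gene 14472), rose from 3.39% ± 0.517 to 6.11% ± 0.832, and held under all 25 alternatives fitted to it. Sox2, a gene of pluripotent and neural progenitor cells (gene 20674), rose from 4.01% ± 0.902 to 6.65% ± 0.454. It rose with 250 bases by 1.28 points (adjusted p 0.532, range 0.000891 to 0.532) and with 2 kb upstream to 500 bases downstream by 1.95 points (0.147), neither of which passed. Hoxd8 rose from 3.80% ± 0.528 to 6.64% ± 1.45 and Foxd3, a neural crest factor, from 4.18% ± 0.436 to 7.11% ± 1.81. The call of Hoxd8 was lost without young replicate 3 (adjusted p 0.0503) and with 250 bases, where it rose by 4.07 points (0.136). That of Foxd3 was lost without young replicate 2, 3 or 4 or old replicate 1 or 2 (up to 0.0592). It was also lost with 2 kb upstream to 500 bases downstream (0.216). Against the background of all promoters, 0.928 of the list's members were expected among those that rose (one-sided Fisher's exact test, adjusted over 72 tests 2.5e-14). This test, here and below, counts genes as independent, though they come from the same mice and may move together. Its p-values thus overstate certainty. The background also ignores that promoters with at least 80 CpGs rose more often (159 of 7612) than those with 30 to 79 (43 of 6152).

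Promoters of imprinted genes also rose on average, from 44.3% ± 0.493 to 46.3% ± 0.964 (SD, n = 5, exact permutation p = 0.00794, adjusted 0.0476, all 5 old mice above all young). Grb10, an imprinted regulator of growth (gene 14783), rose from 6.03% ± 0.900 to 9.47% ± 0.788, and Ndn, necdin (gene 17984), from 25.1% ± 2.24 to 37.2% ± 6.67. Igf2r, the receptor that clears IGF2 (gene 16004), rose from 45.7% ± 3.91 to 52.2% ± 1.396 and Nap1l5 from 80.8% ± 1.88 to 85.8% ± 2.75. These 4 were the only calls among 23 members over all genes, and 5 rose when adjusted over the list alone. The 4 exceeded the 0.301 expected (one-sided Fisher's exact test, adjusted p 0.0041), but not all were equally sure. Igf2r was lost without any 1 mouse other than young replicate 2 or 5 or old replicate 3 (adjusted p up to 0.113), and Nap1l5 without any 1 other than young replicate 2 or old replicate 2 or 5 (up to 0.135). Ndn rose by only 4.72 points with 2 kb upstream to 500 bases downstream (adjusted p 0.532, range 0.000226 to 0.532) and by 8.15 with 250 bases (0.0675). Grb10 rose by 3.39 points with 250 bases, where its call was lost (0.0555, range 0.00198 to 0.0555). The median over members differed by 0.507 points (exact permutation p = 0.508), so that the mean rested on few genes, and the list did not pass against random lists matched on level and CpG count (adjusted p 0.0814). The promoters always shown as a check of the measurement lay near the level of 1 methylated parental copy: H19 59.3% and 58.1%, Peg3 51.0% and 52.2%, Mest 56.5% and 58.2%, Snrpn 58.4% and 61.4% and Kcnq1ot1 55.9% and 55.0% in young and old mice, and none of these passed.

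Promoters of interferon-stimulated genes, the antiviral genes switched on by interferon, lost methylation on average. Their mean fell from 23.9% ± 0.441 in young to 22.6% ± 0.778 in old mice (SD, n = 5, exact permutation p = 0.00794, adjusted 0.0476), with all 5 old mice below all young mice. Oasl1, an antiviral gene that limits the production of interferon (gene 231655), fell from 43.2% ± 3.07 to 33.0% ± 2.53, and Tor3a from 5.19% ± 0.429 to 3.09% ± 0.586. Xaf1, an interferon-induced gene of cell death (gene 327959), rose from 26.4% ± 1.69 to 33.2% ± 2.14. These were the calls among 34 members over all genes, and 1 rose and 4 fell when adjusted over the list alone. The 2 that fell did not pass as an enrichment (0.244 expected, one-sided Fisher's exact test, adjusted p 0.254). Each depended on the window: with 250 bases Oasl1 had an adjusted p of 0.996 (range 0.00249 to 0.996) and Tor3a one of 0.954 (0.00797 to 0.954), while Xaf1 turned to -3.07 points (0.765, range 0.0117 to 0.765), and Tor3a was also lost without young replicate 1, 3, 4 or 5 or old replicate 2 or 4 (up to 0.0872). The calls of the developmental, imprinted and interferon-stimulated lists were lost together without any 1 mouse except old replicate 3 or 4 (lowest adjusted p 0.0714 to 0.143), since 0.00794 is the smallest p the mice allow and 3 lists had to reach it.

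**Figure D1:**
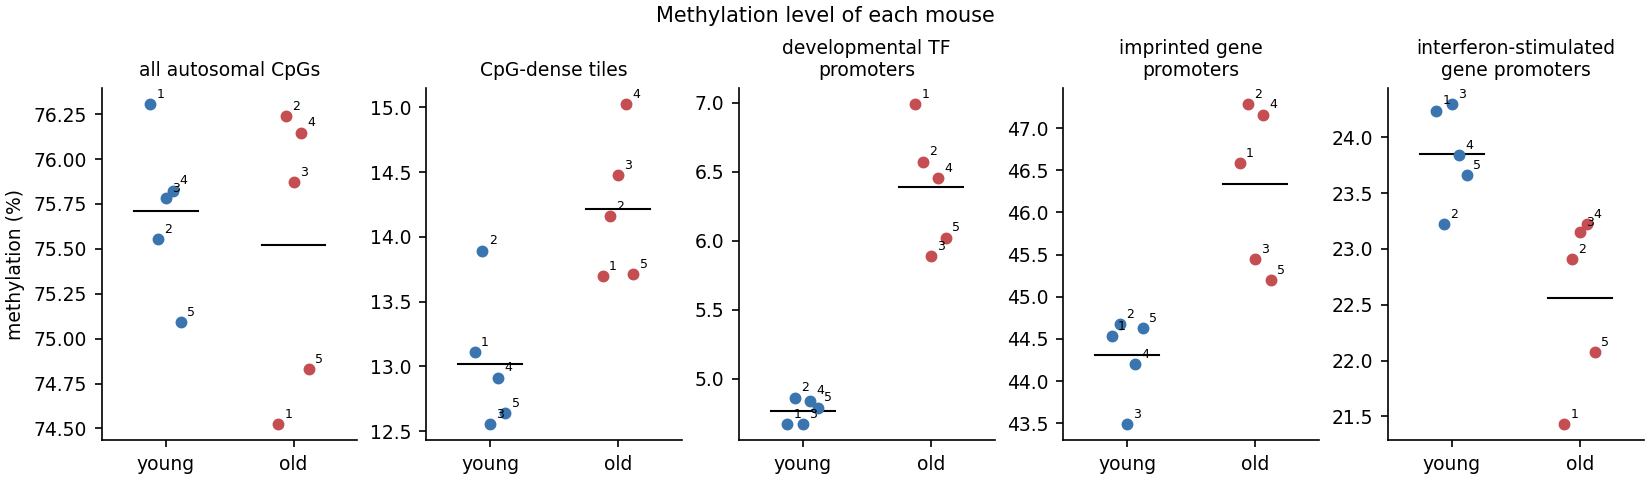
Methylation level in percent of each mouse, numbered by replicate, for all autosomal CpGs, CpG-dense tiles and the promoter means of 3 gene lists, with young mice in blue, old mice in red and group means as lines. The groups overlap for all CpGs and CpG-dense tiles and do not overlap for the 3 lists; each vertical axis has its own range.

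Promoters of interferon receptors, sensors and signalling genes stood at 16.1% ± 0.740 in young and 15.9% ± 0.657 in old mice (SD, n = 5, exact permutation p = 0.738, adjusted 0.886), with no call among 34 members. Their 2 lowest p-values were at Il10rb (11.1% and 7.77%, adjusted p 0.0945) and Tlr9 (37.6% and 43.1%, adjusted p 0.185). For antigen presentation (14.9% and 14.5%, adjusted p 0.732), H2-Q4 stood at 10.5% and 15.4% and H2-M3 at 9.84% and 5.86%. Both passed over all genes, but H2-Q4 rose by only 0.261 points with 250 bases (adjusted p 0.874, range 0.00352 to 0.874) and 1.28 with 2 kb upstream to 500 bases downstream (0.820) and was lost without young replicate 2 or 4 or old replicate 2 or 4 (up to 0.0521). H2-M3 was lost without young replicate 1, 4 or 5 or old replicate 1, 2 or 4 (up to 0.0725) and turned to 0.0814 points with 250 bases. When adjusted over the list alone, 1 of its 22 members rose and 2 fell.

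Genes of inflammation went both ways. Il6, the acute-phase cytokine (gene 16193), fell from 62.3% ± 3.77 to 51.7% ± 5.11, and Cxcl1, a neutrophil chemokine (gene 14825), rose from 5.01% ± 1.398 to 11.9% ± 2.37 (SD, n = 5). Orm2, an acute-phase plasma protein, stood at 55.7% and 47.5% and Rela, a subunit of NF-kB, at 4.94% and 2.62%. The 3 that fell exceeded the 0.122 expected of 17 members (one-sided Fisher's exact test, adjusted p 0.0041), while the list mean was 27.5% and 27.0% (exact permutation p = 0.214, adjusted 0.714), and 2 rose and 3 fell when adjusted over the list alone. Orm2 was lost without young replicate 2, 3 or 5 or old replicate 2 (adjusted p up to 0.1003) and with 2 kb upstream to 500 bases downstream (0.526). Rela was lost without young replicate 1, 3 or 4 or old replicate 1, 2 or 4 (up to 0.0917) and differed by only -0.129 points with 250 bases (0.876, range 0.00508 to 0.876). The 3 losses behind the enrichment were thus not equally sure. With 2 kb upstream to 500 bases downstream Il6 had an adjusted p of 0.195 (range 0.00596 to 0.203) and Cxcl1 one of 0.0602 (0.000120 to 0.0685).

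The promoter mean of the hepatocyte identity list was 11.04% and 12.5% (exact permutation p = 0.254, adjusted 0.714), with 1 member called higher over all genes, and 2 members higher and 1 lower when adjusted over the list alone. Xenobiotic, bile acid and lipid genes (15.014% and 14.997%, adjusted p 1), cell cycle and tumour suppression genes (10.1% and 10.6%, 0.429), DNA methylation machinery (18.1% and 18.3%, 0.796) and housekeeping genes (6.75% and 6.62%, 0.769) held no called promoter, over all genes or adjusted over the list alone. The model that gave these 0 calls called 2104 promoters at an unadjusted p under 0.05 in all, and by edgeR 356 and by limma 270 passed adjustment.

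Promoters of markers of other cell types did not move detectably as groups: leukocytes in general 52.0% and 51.4%, T cells 58.4% and 57.8%, B cells 55.2% and 55.4%, macrophages 50.3% and 50.3%, endothelium 41.6% and 41.1%, stellate cells or fibroblasts 36.6% and 37.3%, and cholangiocytes 21.2% and 21.9% in young and old mice (adjusted p 0.714 to 1). Only 8, 10, 9, 4, 10, 13 and 12 promoters were measured, in that order. These means are therefore a weak check of cell composition. Zap70, a T cell receptor kinase (gene 22637), fell from 68.2% ± 2.04 to 57.8% ± 1.72 (SD, n = 5), which was lost with 250 bases (adjusted p 0.855, range 0.000689 to 0.855). Zap70 was also the only call adjusted over its list alone. Of the 12 cholangiocyte promoters 1 was called higher.

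**Figure D2:**
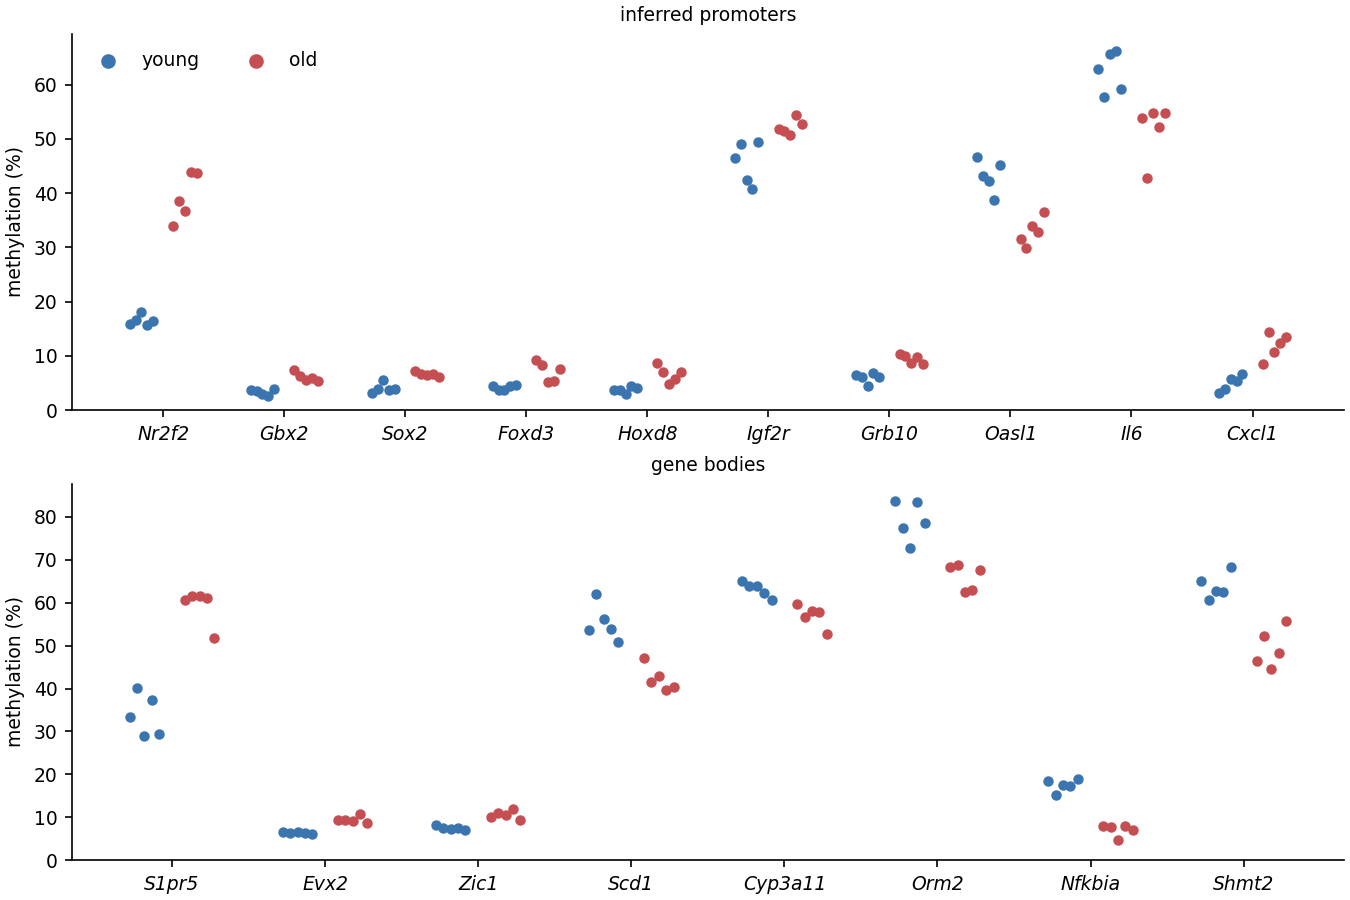
Methylation level in percent of each mouse at 10 named inferred promoters and 8 named gene bodies, young mice in blue and old mice in red. At Nr2f2 the old mice average 39.4% against 16.6% in young mice, and at the gene body of Scd1 42.3% against 55.3%.

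Gene bodies more often lost than gained methylation: of 18182 tested, 182 were higher and 677 lower in old mice. Scd1, the desaturase that makes oleate (gene 20249, chromosome 19, 44395450 to 44406709), fell from 55.3% ± 4.19 in young to 42.3% ± 2.98 in old mice (SD, n = 5 each, 175 CpGs, 3079 to 3932 reads, adjusted p = 0.0002). Shmt2, a mitochondrial enzyme of 1-carbon metabolism (gene 108037), fell from 63.8% ± 2.89 to 49.4% ± 4.55, Cpn2, a subunit of plasma carboxypeptidase N (gene 71756), from 32.4% ± 2.76 to 18.2% ± 2.32, and Orm2 (gene 18406) from 79.2% ± 4.57 to 66.0% ± 3.06. Mknk2, a kinase of translation initiation (gene 17347), fell from 54.7% ± 1.59 to 42.5% ± 3.202, Tob2, an antiproliferative gene (gene 57259), from 45.5% ± 2.30 to 33.7% ± 2.69, and Mief2, a gene of mitochondrial division (gene 237781), from 42.8% ± 3.19 to 31.1% ± 3.95. Dnase1l2 and Tedc2 fell by 12.6 and 12.2 points, and Serpina7, thyroxine-binding globulin, by 12.8. The 5 old mice lay below all young mice at each of these 10. The losses at Cyp2d9 and Mup19 are uncertain, since both belong to families of near-identical genes.

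The largest gain of a gene body was at S1pr5, a sphingosine-1-phosphate receptor (gene 94226, chromosome 9, 21243917 to 21247443), from 33.8% ± 4.87 to 59.3% ± 4.29 (SD, n = 5 each, 146 CpGs, adjusted p = 6.8e-06). Ltb4r2, a leukotriene receptor (gene 57260), rose from 36.1% ± 2.82 to 51.3% ± 2.30, Mapk15, an atypical MAP kinase (gene 332110), from 56.2% ± 4.34 to 69.2% ± 1.30, and Hsf4, a heat shock transcription factor (gene 26386), from 71.2% ± 1.81 to 82.0% ± 1.54. Phospho1 rose by 11.3 points, Slc27a3 by 9.69 and Slc39a4, a zinc transporter, by 9.56. Jak3, a kinase of cytokine receptors, rose by 9.87 points, which limma did not call (adjusted p 0.0570, range 3.6e-08 to 0.151). Speer4c, Speer4d, Rpl35 and Rps18 also passed, but have many near-identical copies. Speer4d was lost without old replicate 2 (adjusted p 0.0599). With the genome-wide level of each mouse as an offset the split of gene bodies was 224 higher and 492 lower, and without young replicate 1 the calls dropped from 859 to 540.

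Gene bodies of developmental transcription factors rose one by one, as their promoters did: 19 of 66 were called higher and none lower, and 27 rose when adjusted over the list alone. Evx2, a homeobox gene beside the Hoxd cluster (gene 14029), rose from 6.40% ± 0.231 to 9.46% ± 0.828, and Zic1, a zinc finger gene of the cerebellum (gene 22771), from 7.53% ± 0.413 to 10.6% ± 1.02 (SD, n = 5). Hoxa11 stood at 7.55% and 11.7% and was lost without young replicate 1, 3 or 4 (adjusted p up to 0.0821). The enrichment over the 0.661 expected had an adjusted p of 3.2e-21 (one-sided Fisher's exact test over 72 tests), which again counts genes of the same mice as independent. The list mean was 16.5% ± 0.141 and 17.8% ± 0.550, with all 5 old mice above all young, which did not pass adjustment (exact permutation p = 0.00794, adjusted 0.143). This is the smallest p the mice allow, and a list alone at it could not pass, so that the adjusted value does not speak against a difference.

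Gene bodies of xenobiotic, bile acid and lipid metabolism lost methylation one by one, with 7 of 36 lower and none higher over all genes, and 14 lower and 1 higher when adjusted over the list alone. Besides Scd1, Cyp3a11, a drug-metabolising cytochrome P450 (gene 13112), fell from 63.1% ± 1.78 to 57.0% ± 2.64, and Mlxipl, the glucose-sensing transcription factor ChREBP (gene 58805), from 56.1% ± 1.499 to 51.7% ± 1.94 (SD, n = 5). The 7 exceeded the 1.34 expected (one-sided Fisher's exact test, adjusted p 0.0045). The list mean was 58.4% ± 0.618 and 56.4% ± 1.53 (exact permutation p = 0.0397, adjusted 0.179). Cyp3a11 has near-identical neighbours, and limma did not call Mlxipl (adjusted p 0.0575, range 2.8e-07 to 0.0952).

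Among inflammation genes, the body of Nfkbia, the inhibitor of NF-kB (gene 18035), fell from 17.5% ± 1.41 to 7.05% ± 1.37 (SD, n = 5, adjusted p = 2.4e-06), and with Orm2 made up the 2 calls of 22 members, which were also the 2 adjusted over the list alone. In the interferon lists, Gbp2 stood at 88.1% and 84.7%, Igtp at 77.0% and 82.0%, Ifnar1, a chain of the type I interferon receptor, at 85.6% and 83.7%, and Irf2 at 72.4% and 70.6%. All 4 passed over all genes, but each was lost without at least 6 of the mice taken 1 at a time: Gbp2 without young replicate 1, 3 or 4 or old replicate 1, 4 or 5 (adjusted p up to 0.0969), Igtp without young replicate 1, 2, 3 or 5 or old replicate 2 or 3 (up to 0.106), Ifnar1 without any young replicate or old replicate 3 or 4 (up to 0.132), and Irf2 without young replicate 1, 2, 3 or 5 or old replicate 3, 4 or 5 (up to 0.0888). With the genome-wide level as an offset Ifnar1 (0.0986) and Irf2 (0.0891) were also lost. Adjusted over their lists alone, 2 interferon-stimulated genes rose and 3 fell, and 2 receptor and signalling genes fell. Irf7 (65.6% and 63.5%), Ifit1 (84.8% and 87.9%) and Mx1 (87.1% and 87.4%) did not pass.

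Other listed gene bodies passed singly. Hpx, hemopexin, fell from 73.4% ± 3.35 to 64.9% ± 4.00, and Dnmt3a, a DNA methyltransferase, from 71.1% ± 0.289 to 68.9% ± 0.887 (SD, n = 5). Nfe2l2, the oxidative stress factor NRF2, stood at 50.9% and 47.1% and was lost without young replicate 1, 3 or 5 or old replicate 4 or 5 (adjusted p up to 0.0809) and with the genome-wide level as an offset (0.0856). Rpl13a rose from 42.8% ± 1.98 to 50.4% ± 2.72, while Rplp0 (66.5% and 72.2%) was lost without young replicate 3, 4 or 5 or old replicate 1, 2, 3 or 4 (up to 0.0963), and both have processed copies. No body of the antigen presentation or imprinted lists passed by this model. Markers of other cell types moved singly: Lcp1 of leukocytes fell from 82.5% ± 0.653 to 80.3% ± 0.617, Fcer1g of macrophages from 58.5% ± 2.41 to 49.6% ± 4.66, and Pecam1 of endothelium stood at 82.5% and 80.8% but was lost without any 1 mouse other than young replicate 2 (up to 0.126) and with that offset (0.0581). Dnmt3a was lost by limma (adjusted p 0.0825, range 0.00829 to 0.0825) and with the mice of the later date alone (0.0528).

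Means over the gene bodies of a list passed for 0 of 18 lists by exact permutation test, 4 of them at an unadjusted p under 0.05. Besides the developmental and xenobiotic lists these were interferon receptors and signalling (79.02% and 78.4%, exact permutation p = 0.0397, adjusted 0.179) and inflammation (70.1% and 68.7%, p = 0.0397, adjusted 0.179), while against random lists matched on level and CpG count 2 lists passed. The others were interferon-stimulated genes (79.5% and 79.2%, adjusted p 0.732), antigen presentation (69.6% and 69.3%, 0.829), hepatocyte identity (41.6% and 41.7%, 0.983), imprinted genes (71.5% and 71.8%, 0.868), cell cycle and tumour suppression (61.7% and 61.8%, 0.983), DNA methylation machinery (80.8% and 80.8%, 0.984) and housekeeping genes (64.4% and 64.8%, 0.732). For leukocytes the means were 79.1% and 78.9%, T cells 79.7% and 79.7%, B cells 75.5% and 75.7%, macrophages 76.4% and 75.3%, endothelium 74.4% and 73.8%, stellate cells or fibroblasts 72.9% and 72.5%, and cholangiocytes 69.6% and 69.4% (exact permutation, adjusted p 0.400 to 0.983). Alb, albumin, stood at 11.5% ± 3.01 and 14.9% ± 4.67, and Ptprc, the leukocyte antigen CD45, at 77.0% ± 0.608 and 77.4% ± 1.12 (SD, n = 5), and neither passed.

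Of 2132465 tiles of 1 kb, 3925 were higher and 18822 lower in old mice. The count depended on the model: by limma 568 were higher and 3112 lower, and without moderation 78 and 397. CpG density parted the directions, though dense tiles are mostly lowly and sparse tiles highly methylated, which limits how far either can fall or rise. Among tiles with at least 40 CpGs 653 rose and 109 fell, among those with 15 to 39 CpGs 1043 rose and 5643 fell, and among those with fewer 2229 rose and 13070 fell. On chromosome X 76 rose and 327 fell. Among tiles at 20 to 80% in young mice, with room to move either way, 2421 rose and 12646 fell. This argues against limits on how far a level can move as the whole source of the excess of losses. Of all calls, 1771 higher and 12471 lower tiles differed by at least 10 points.

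**Figure D3:**
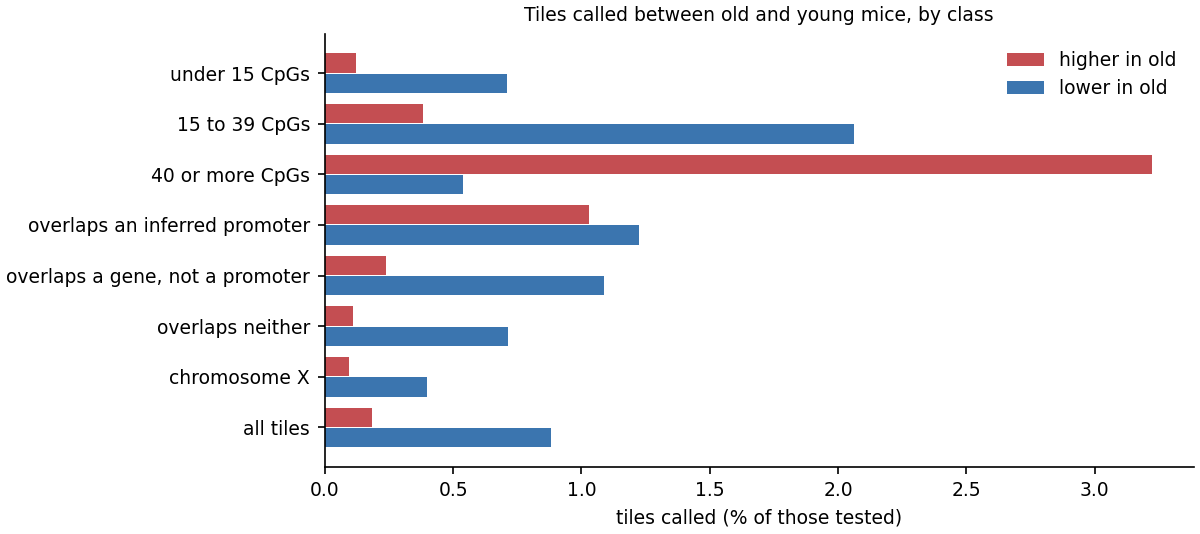
Share in percent of the tested 1 kb tiles of each class that were called higher (red) or lower (blue) in old than in young mice, all bars starting at 0. CpG-dense tiles were called higher in 3.22% and lower in 0.538%, against 0.184% and 0.883% of all tiles.

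Of the 8 largest gains of single tiles 3 lay inside genes. A tile 4724 bases from F5, coagulation factor V (chromosome 1, 164225001 to 164226000), stood at 8.20% ± 7.91 in young and 91.4% ± 5.06 in old mice (SD, n = 5, 8 CpGs, 32 to 75 reads). Tiles inside Pik3c3, a lipid kinase of autophagy (chromosome 18, 30267001 to 30268000), rose from 5.82% ± 4.85 to 77.9% ± 9.03, and inside Camk2b, a calcium-dependent kinase (chromosome 11, 6006001 to 6007000), from 2.46% ± 1.91 to 72.8% ± 12.4. A tile inside Pik3c2a rose from 48.7% ± 8.54 to 94.8% ± 2.04, and tiles nearest to Scpep1, Alkbh5 and Zfp236, at 27020, 25489 and 2086 bases, rose by 52.8 to 55.9 points. The greatest loss was 60919 bases from Pgm2 (chromosome 5, 64031001 to 64032000), from 96.0% ± 2.66 to 7.49% ± 6.79. Tiles inside Dmd, the dystrophin gene (chromosome X, 82934001 to 82935000), fell from 85.8% ± 7.75 to 18.1% ± 5.00, and inside Npsr1 from 94.8% ± 2.75 to 37.5% ± 14.95. Tiles nearest to Fbxo8, Ythdc2, Crisp1, Adam34l and inside a predicted gene fell by 75.6, 69.7, 60.3, 58.9 and 56.8 points. The remaining tile was the chromosome 1 copy of a mitochondrial stretch, described with read depth. The tiles of Pik3c3, Camk2b and Pgm2 held 10, 19 and 2 of the CpGs read all-or-none by group that are described with read depth. A further 6 lay within 1 kb of the tile near F5, the nearest at 391 bases. Without the CpGs inside the tiles the differences of the 3 were 71.04, 65.9 and -86.6 points, all still called. The CpGs left in missed the limits of that set in at least 1 mouse and may follow the same pattern. Their removal therefore does not set the 3 tiles apart from it. In all 16 the groups did not overlap, by the rule that chose them, and each call held without any 1 mouse.

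At the scale of 100 kb, 32 of 25505 bins were higher and 152 lower in old mice. The following bins were chosen after their values were seen. The bin with the Ugt1a genes, which conjugate bilirubin and drugs (chromosome 1, 88100001 to 88200000), fell from 63.2% ± 0.858 to 58.1% ± 2.13 (SD, n = 5, adjusted p = 0.006). Bins with Rbm47 (51.4% and 47.0%), with Abcc2, a bile canalicular exporter, and Dnmbp (70.4% and 66.3%), and with Trak1 (69.4% and 65.4%) fell as well, while the bin with Camk2b rose from 61.5% ± 0.615 to 71.3% ± 1.82. The largest rise, from 24.3% in young to 70.1% in old mice, was in the bin with the chromosome 1 copy of a mitochondrial stretch. A bin on chromosome 17 with 624944 to 901993 reads per mouse, against a median of 13931, rose from 13.7% to 26.7%. The largest fall, from 76.7% to 65.0%, was in a chromosome 13 bin with Tmem267. A chromosome 5 bin that overlaps a stretch whose read depth parted the groups rose from 64.6% to 71.7%. The count rested on single mice: it was 57, 118, 80, 67 and 90 without young replicate 1, 2, 3, 4 or 5, 532 (259 higher and 273 lower) without old replicate 1, and 93 without old replicate 3. With the genome-wide level as an offset 78 bins were higher and 197 lower, by limma 22 and 30, and at 1 Mb 4 and 1. The direction of the bins thus depended on the setting. Spread between mice, the variance of tiles beyond counting error, was 3.11 times as large in old as in young mice (exact permutation p = 0.222), and 0.276 times as large without old replicate 1.

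The age groups also differed in where reads lay, in depth, and at single CpGs read all-or-none. On the mitochondrial genome 11 of 247 CpGs, from position 9268 to 10144, had 39 to 195 reads in young mice and 7197 to 26400 in old mice. A nuclear copy of that stretch on chromosome 1 (24612433 to 24613310) had 18535 to 43645 reads in young mice, at 1.23% ± 0.217 methylated, and 101 to 235 reads in old mice, at 47.3% ± 6.36 (SD, n = 5). Read depth relative to the mouse's own median tile parted the groups by over 1.4 times, the lowest mouse of 1 group against the highest of the other, at 502 of 1218964 tiles of 2 kb. Runs of at least 5 of them formed 11 stretches. A stretch on chromosome 19 (37236001 to 37378000) with Ide, insulin-degrading enzyme, and Kif11 had a relative depth of 1.09 ± 0.0170 in young and 2.17 ± 0.0494 in old mice. Speer4c and Speer4d lay in one on chromosome 5 with 3.23 ± 0.0955 and 1.10 ± 0.0105. Tmem267 overlapped one on chromosome 13 with 8.94 ± 0.356 and 4.18 ± 0.464. At 447 single CpGs every mouse of 1 group read at most 10% and every mouse of the other at least 60%, 394 of them low in young and 53 low in old mice. Leaving these CpGs out changed the tile calls from 22747 to 22415 and the promoter calls from 333 to 332.

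**Figure D4:**
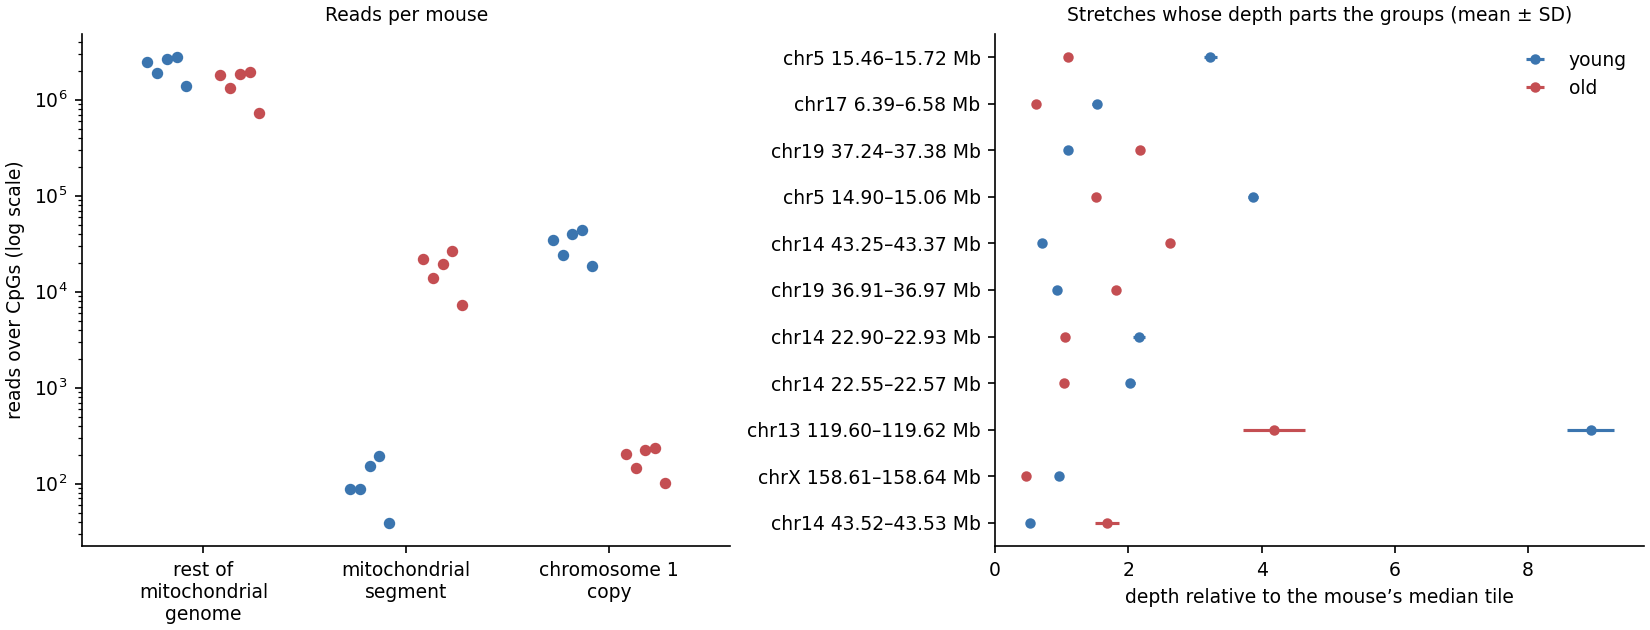
Left, reads of each mouse over CpGs of the mitochondrial genome outside and inside the stretch from 9268 to 10144 and over its chromosome 1 copy, on a log scale; right, mean and SD (n = 5) of relative read depth over the 11 stretches that part the groups, young in blue and old in red. The copy had 18535 to 43645 reads in young and 101 to 235 in old mice.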

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

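Of the tests in this part, those of read alignment, of read depth as a source of the lower tiles, of sequence differences near the measured CpGs and of other cells in old replicate 1 were chosen before their results were seen, and the others only after.

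Reads parted all young from all old mice at places spread over the genome, as a difference in DNA sequence or copy number between the groups would give. The fewest reads of any young mouse on the chromosome 1 copy of a mitochondrial stretch were 18535, against at most 235 in old mice, a signal outside the main measurement. A change of mitochondrial methylation would leave the reads in place, but the highest young share of mitochondrial reads in the stretch was 0.0071 of the lowest old share, while no mitochondrial CpG outside it fell below a log2 ratio of -0.97, as a sequence difference confined to that stretch would give. Of the CpGs read all-or-none by group, 420 had neighbours within 200 bases outside that set. These neighbours differed by under 20 points for 85.2% and by more for 14.8%. Others of the set were left out as neighbours, so CpGs that moved together were not counted. Still, 390 of the 447 had no other of the set within 1 kb. For most of the set the shares thus speak for a changed base at the CpG and against methylation as the main source. Runs of the set, as at Camk2b and Pik3c3, moved together, and the shares cannot decide on them. Of all 447 CpGs read all-or-none by group, 5.15% had a read depth that differed over 1.5 times, against 1.15% of 94853 random CpGs. These were too few for alignment to account for most of the set. Of the tiles whose depth parted the groups 95.0% lay within 10 kb of another. Among the 126 splits of the mice only the real one gave as many (1 split, 502 tiles, highest other 9), which makes chance unlikely. Copy number that differs between the groups is a candidate explanation.

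More tiles were lower than higher in old mice, 82.7% of all calls. A lower genome-wide level is argued against as the whole cause by 80.5% with that level as an offset. Old replicate 1 alone is argued against in the same way by 82.4% without it. So is a difference in depth by 86.0% with every tile thinned to 50 reads (621 higher, 3829 lower). Over 100 kb from every all-or-none CpG the share was 83.5%, which cannot decide on sequence differences. Only 65718 of 2132465 tiles lay nearer, so leaving them out could change the share little, and these CpGs can mark only changes at a CpG. Tiles within 100 kb were called more often (1.56%) than those beyond (1.05%), so that sequence differences may still add to the calls. Age and breeding lineage of the mice rather than their age cannot be told apart: 0 mice of one age had the mitochondrial read pattern of the other, so both follow the same split. Age stays open as an untested explanation, and lineage may add to any of the differences reported.

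Old replicate 1 stood apart from the other mice. Its mean distance from them over 100 kb bins was 2.39 points, against 1.395 to 1.57 for the other old mice, and the first principal component, on which it lay alone, held 48.9% of the variance. Its share of mitochondrial reads in the stretch was 1.19%, within the range of the old mice, which argues against a mislabelled young mouse, and it ranked 9 of 10 in depth from the lowest, which argues against shallow sequencing. More cells of another type cannot be told apart from a change within hepatocytes. Promoters of hepatocyte genes lay 1.69 SD above the other 4 old mice, those of leukocytes in general -9.87 SD from them, and those of cholangiocytes 3.85 SD above them. The leukocyte value, 49.3% against 52.0%, rested on 8 promoters and an SD of only 0.265 points among the other 4. Promoters of T cells, B cells, macrophages, endothelium and stellate cells or fibroblasts lay -0.317 to -1.88 SD from them. Age-related change in this mouse stays open and untested.

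In 20 of 364 groups of 5 mice 1 mouse lay far from the rest by Dixon's criterion, where chance gives about 18.2. Old replicate 1 accounted for 9 of these. Besides its mean distance they were the level of chromosome X (76.1%), the promoter mean of leukocytes (49.3%), the gene body mean of macrophages (72.7%), the gene bodies of Slc39a4 (65.1%), Lcp1 (79.2%), Snrpn (63.5%) and Ptprc (75.4%), and the tile in Dmd (27.1%). Old replicate 2 was low at the promoter of Il6 (42.8%) and high at that of Zap70 (60.8%). Old replicate 3 was low at the gene body of Nfkbia (4.68%), and old replicate 4 at the tile in the predicted gene on chromosome 2 (15.1%). Old replicate 5 was low for the promoter mean of interferon receptors and signalling (14.8%) and the gene body of S1pr5 (51.7%), and high at the promoter of Slc3a1 (56.2%). Young replicate 1 was high for the gene body mean of interferon receptors and signalling (79.8%) and young replicate 3 low for the promoter mean of T cells (57.0%). Young replicate 5 was high at the promoter of Rpl32l (64.4%) and low at the gene body of Rplp0 (59.4%).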

How the results depend on the processing

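The settings of surer 5′ ends, both gene ends, all-or-none CpGs and high depth, and the counts over other splits of the mice, were chosen after the results were seen, and the others before. Of the values that answer a comparison, 146 kept their direction and size or side of the threshold, 39 moved and 1 reversed. Counts with a difference of at least 10 points were 14242 tiles, 64 promoters, 30 gene bodies and 3 bins, fewer by construction. Without moderation they were 475 tiles, 81 promoters, 321 gene bodies and 52 bins, and by limma 3680 tiles, 538 gene bodies and 52 bins. The cause was not tested. Tiles of 2 kb gave 14383 calls among fewer tiles and bins of 1 Mb gave 5 (4 higher, 1 lower) among fewer bins. Promoters from 2 kb upstream to 500 bases downstream gave 134 calls, and both ends of every gene 872 among more regions. With only the mice of the later date, which are fewer, 212 promoters and 69 bins were called. Promoter lists past the threshold were 0 by the median over members, with surer 5′ ends, with the replicate block and with the later date alone, where the smallest p of the last 2 is 0.0625, which cannot pass, and 0.0286, which could pass only if most lists reached it. Against random matched lists 2 gene body lists passed.

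Leaving out 1 mouse gave 17425 to 22081 tiles, 213 to 355 promoters, 540 to 1040 gene bodies, 57 to 532 bins, 0 to 3 promoter lists, 0 gene body lists and 0 compartments. The fewest promoters came without young replicate 4, the fewest gene bodies and bins without young replicate 1, and the most bins without old replicate 1. The global difference was -0.369 to 0.060 points, that of intermediate tiles -0.826 to 1.34, and the ratio of spread 0.276 to 23.03, reversed at 0.276 without old replicate 1. With the mean over tiles the ratio was 1.52. No ratio could be given with thinned tiles, with the later date alone, or without young replicate 1 or 5, since a variance fell below counting error. With 250 bases the promoter differences of H2-M3 (0.0814), Ptk7 (-1.06) and Xaf1 (-3.07) reversed, as did H2-M3 with 2 kb upstream to 500 bases downstream (0.371), and the cause was not tested.

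Replicate numbers did not pair the mice by the rule that every pair correlate over 0.1: correlations of levels between mice of 1 number ran from -0.091 to 0.16 over bins, with 3 of 5 pairs over 0.1, and 2 over gene bodies. Not every mouse lay closest to its own number, but 6 of 10 did over bins, a hint that some numbers share more than a name, as do the mice numbered 5 their cull date. With the replicate block as a term 24609 tiles, 395 promoters, 986 gene bodies and 245 bins were called, against 22747, 333, 859 and 184 without it, and of the named calls the gene bodies of Irf2 (adjusted p 0.0699) and Pecam1 (0.0566) did not pass with it. Of named regions called, 31 of 44 promoters, 35 of 44 gene bodies and 16 of 16 tiles held without any 1 mouse, and 10, 22 and 12 held under all alternatives, the minimum of 10 points aside. Without moderation 53 of 104 were lost, by limma 18, and with the later date 16.

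Among the splits of the mice into 5 and 5 that were drawn, none came near the real one (1 split as large in each case, the real one). Tiles were 22747 against at most 1608 in 60 splits drawn, promoters 333 against 2, gene bodies 859 against 16 and bins 184 against 3, each in 100. Not all of the 126 splits were drawn, and in a mixed split the age difference adds to the spread within groups. Chance is thus made unlikely but not excluded. Any steady difference between the groups would also set the real split apart. In simulated data with 200 changed regions of each kind 0% of tiles, 50.7% of promoters and 80.6% of gene bodies were recovered at 5 points.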

Other observations

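The test of gene families was chosen after the data were seen, as was the use of the matched lists, themselves planned, to weigh an explanation of the developmental list, and the test of the spacing of lower tiles before its result.

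Gene bodies of the UDP-glucuronosyltransferases, which conjugate bilirubin, steroids and drugs, were lower in old mice in 10 of 22 measured members, against 0.819 expected (one-sided Fisher's exact test, adjusted over 354 tests 7.3e-07). They were Ugt2b5, Ugt2b36, Ugt3a1 and 7 genes of the Ugt1a cluster, which share sequence over the same locus and so are not independent. Of gene bodies of ribosomal proteins of the large subunit, 5 of 30 were higher, namely Rpl35, Rpl13a, Rpl7, Rpl21 and Rpl6 (0.300 expected, adjusted p 0.00196), all of them with processed copies elsewhere in the genome. Genes whose symbols have H before the first digit, mostly histone and histocompatibility genes, had 6 of 83 promoters higher and aldehyde dehydrogenases 5 of 21 gene bodies lower, which did not pass (adjusted p 0.0773 each).

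Promoters of hepatocyte identity genes, which did not pass by permuting mice, rose by 1.43 points, which passed against random lists matched on level and CpG count (adjusted p 0.0132). Old replicate 1 stood at 15.1% and the other 4 old mice at 11.8%, against 11.04% in young mice, so that much of the rise came from 1 mouse. Mitochondrial CpGs read 0.824% ± 0.0862 methylated in young and 0.885% ± 0.0623 in old mice (SD, n = 5, exact permutation p = 0.230).

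The rise at developmental transcription factors might reflect a rise of all CpG-rich, lowly methylated promoters alike. The share of 10000 random lists matched on level and CpG count that lay as far from their mean was 0.0001, the smallest it can be, which argues against that explanation as the whole cause. Tiles lower in old mice might also be spread evenly over the genome, but 35.6% of them lay within 5 kb of another, against a mean of 9.97% and at most 10.8% in 100 random sets of tiles of like CpG count and young level, so that these losses lay together.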
